A study of Homo sapiens with 8 samples.

How the data were processed

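The series held 8 RNA libraries of HEK293 cells: 4 of total RNA, with 1 library for each combination of genotype label (wild type or RBM7 knockout) and treatment (none or 50 µM etoposide), and 4 of immunoprecipitated RNA, with 2 biological replicates each of FLAG-empty and FLAG-RBM7. Per the submitters' processing notes, ribosomal RNA was depleted with Ribo-Zero Gold, reads were aligned to hg38 with TopHat2 2.1.1 and Bowtie2 2.2.9, and the authors computed FPKM with Cufflinks 2.2.1. The deposited values are thus FPKM, scaled by library and transcript length, and no read counts were used here. Depth per library and the counting error of a low value are therefore unknown, and the strand of the reads was not given in the sources used here.

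Each file listed the same 16283 RefSeq transcripts, 15426 under a symbol and 857 under an accession, of which 814 were matched to a symbol and 43 were not. Transcripts sharing a symbol were summed to 11437 genes, and 11382 of these (99.5%) had a GENCODE v29 entry for position and type. The lowest value of a symbol transcript in the untreated library labelled knockout was 1.0002 FPKM, whereas 1189, 1341 and 1433 symbol transcripts lay under 1 FPKM in untreated wild type, etoposide-treated wild type and the etoposide library labelled knockout. The listing was thus cut on the untreated library labelled knockout. Transcripts listed by accession were not cut in this way, with a lowest value of 0.0319 FPKM.

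FLAG-empty replicate 1 held 0 for 15327 transcripts. The symbol transcripts with a value in it reached at most 1.3285 FPKM in the untreated library labelled knockout. By this definition none of the 14404 above that level had a value, while 506 of 1022 (49.51%) at or below it had one. Among transcripts listed by accession, 407 also held 0 in this replicate. Its zeros were taken as missing values, a departure from the design, which counted an unlisted gene as 0; this was decided before any fit. The choice of lists, tests, thresholds, named genes and the alternatives of the first plan was made before the data were examined.

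Fits used limma 3.58.1 in R 4.3.3 on log2(FPKM + 1) of genes with a mean of at least 1 FPKM, with empirical Bayes and a trend, and a Benjamini-Hochberg adjusted p under 0.05 as threshold. FLAG-RBM7 was set against FLAG-empty over 9817 genes, of which 345 had 4 values and 9472 had 3. The 4 total RNA libraries were fitted with genotype plus treatment over 10818 genes, which leaves 1 residual degree of freedom, the interaction. Single pairs of libraries were given as log2 ratios of FPKM + 1 without a test, with counts of genes changed at least 2-fold. List medians in pairs were placed among 10000 random lists drawn in 20 expression bins.

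The lists numbered 33 and were fixed before the data were seen. Of these, 25 had at least 5 measured members and were tested with camera at a preset correlation of 0.01. With an estimated correlation, camera takes its p from the residual degrees of freedom, here 1, so it could hardly call any list. The immunoprecipitated libraries were tested with the preranked form of camera, because of missing values. The total RNA lists were first run in that form on raw t statistics and then with camera itself, as designed, which turns them into z scores. The change was made after the first values had been seen, and it brought 3 lists past the threshold: very long genes for genotype, and immediate early and interferon genes for etoposide. Lists of mitochondrial messages and of blood cell markers had 0 listed members, and those of fibroblast and endothelial markers, of hepatocyte, keratinocyte and lung markers and of uncharacterised loci had 1 each. The small Cajal body RNAs and spliceosomal snRNAs had 2 each and other short RNAs 4, so none of these was tested. A pattern meant for microRNA precursors matched host genes only and was renamed, and patterns for box C/D and H/ACA snoRNAs matched nothing.

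Genes were named by a rule fixed in advance: RBM7 in every library and NEAT1 first, the 8 highest and 8 lowest called genes per fit, the 4 highest and 4 lowest per pair and interaction with a mean of at least 5 FPKM, and up to 4 members per list with the largest change, short RNA classes left out. JUN was named after its values had been seen. Some genes that the rule selects are not reported here.

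Alternatives planned in advance were pseudocounts of 0.1 and 5, no filter or a mean of at least 5 FPKM, centred libraries, quantile normalization, rescaling without short RNAs, only genes above 0 in every library, the highest transcript of a symbol, no trend or a robust fit, an estimated correlation, a replicate block and leaving out each immunoprecipitated library. Added after seeing the data were keeping the zeros of FLAG-empty replicate 1, removing the median of each chromosome or of 51 neighbouring genes, leaving out genes under 0.01 FPKM, and leaving RBM7 out of the genes higher with FLAG-RBM7. Where an alternative called too few genes higher with FLAG-RBM7 to follow, the measured ones among up to 200 genes with the lowest p of those higher were followed instead. In the rescaling, FLAG-empty replicate 1 was given the factor of replicate 2 after a first output had been seen.

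The fits were tested on simulated data with changes of 2, 4 and 8-fold. The immunoprecipitation fit recovered 1.5%, 25.4% and 68.2% of them with 3 false calls among 9535 genes. The genotype fit recovered 66 of 67, 67 of 67 and 66 of 66 changes (98.5%, 100% and 100%). It made 38 false calls among 10733 genes. The etoposide fit recovered 65 of 67, 67 of 67 and 66 of 66 changes (97%, 100% and 100%). It made 33 false calls among 10726 genes. In the genotype and etoposide fits, false calls were thus a larger share of all calls than the adjusted p threshold aims at. The simulation first used 1 spread for all genes and was then changed to the spread of each gene. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.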

Results

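RNA was sequenced from HEK293 cells, a human embryonic kidney line, in 8 libraries. Of these, 4 held total RNA from wild type cells and from cells labelled as lacking RBM7, each either untreated or given 50 µM etoposide, a topoisomerase II poison that leaves DNA double-strand breaks, with 1 library in each of the 4 groups. The other 4 libraries held RNA recovered by FLAG immunoprecipitation (RIP), 2 from a FLAG-empty control and 2 with FLAG-RBM7. RBM7 is the RNA-binding subunit of the nuclear exosome targeting (NEXT) complex, which delivers nuclear transcripts to the RNA exosome for decay. The comparisons therefore address which RNAs are recovered with RBM7, what differs between the libraries labelled knockout and wild type, and how both respond to DNA damage.

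Values were FPKM per RefSeq transcript, the same 16283 transcripts in every library, summed to 11437 genes. The depth behind them is unknown because no read counts were given in the sources used here. The median FPKM per gene was 8.04 and 8.65 in the wild type libraries without and with etoposide and 8.26 and 8.07 in the libraries labelled knockout. It was 6.62 in FLAG-empty replicate 2 and 5.2 and 3.59 in the FLAG-RBM7 libraries. FLAG-empty replicate 1 stood apart, with 554 genes at 1 FPKM or more against 9923 in FLAG-empty replicate 2. Short RNAs held 94.6% of its listed FPKM. Its zeros were treated as missing values, so neither figure describes the RNA content of that library. Of 198 transcripts listed by accession at 2 FPKM or more in replicate 2, 141 had a value in replicate 1. Among these the median ratio of replicate 1 over 2 was 1.026, with a Pearson r of 0.944 on the log2 scale. Over the 345 genes with a value in both replicates, Pearson r was 0.821. Every transcript listed under a gene symbol reached 1 FPKM in the untreated library labelled knockout, while 1189 of them lay under 1 FPKM in the untreated wild type library. The limma p-values of single genes rest on the spread between these libraries and nothing wider. For most immunoprecipitated genes that spread is its trend over all genes. The camera p-values of lists and the permutation p-values measure the spread between genes, not between libraries.

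RBM7 RNA itself did not fall in the libraries labelled knockout. Its level was 3.28 FPKM in wild type and 2.92 FPKM in the untreated library labelled knockout, and 3.19 and 3.39 FPKM with etoposide. The averaged difference was -0.03 on the log2 scale (SE 0.196, limma adjusted p = 0.935). Processed RNA levels cannot show whether the reading frame is altered or a library is mislabelled, so these libraries are called labelled knockout throughout. In the immunoprecipitated RNA, RBM7 reached 442.6 ± 11.9 FPKM with FLAG-RBM7 (SD, n = 2) against 0.000693 FPKM in FLAG-empty replicate 2.

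**Figure D1:**
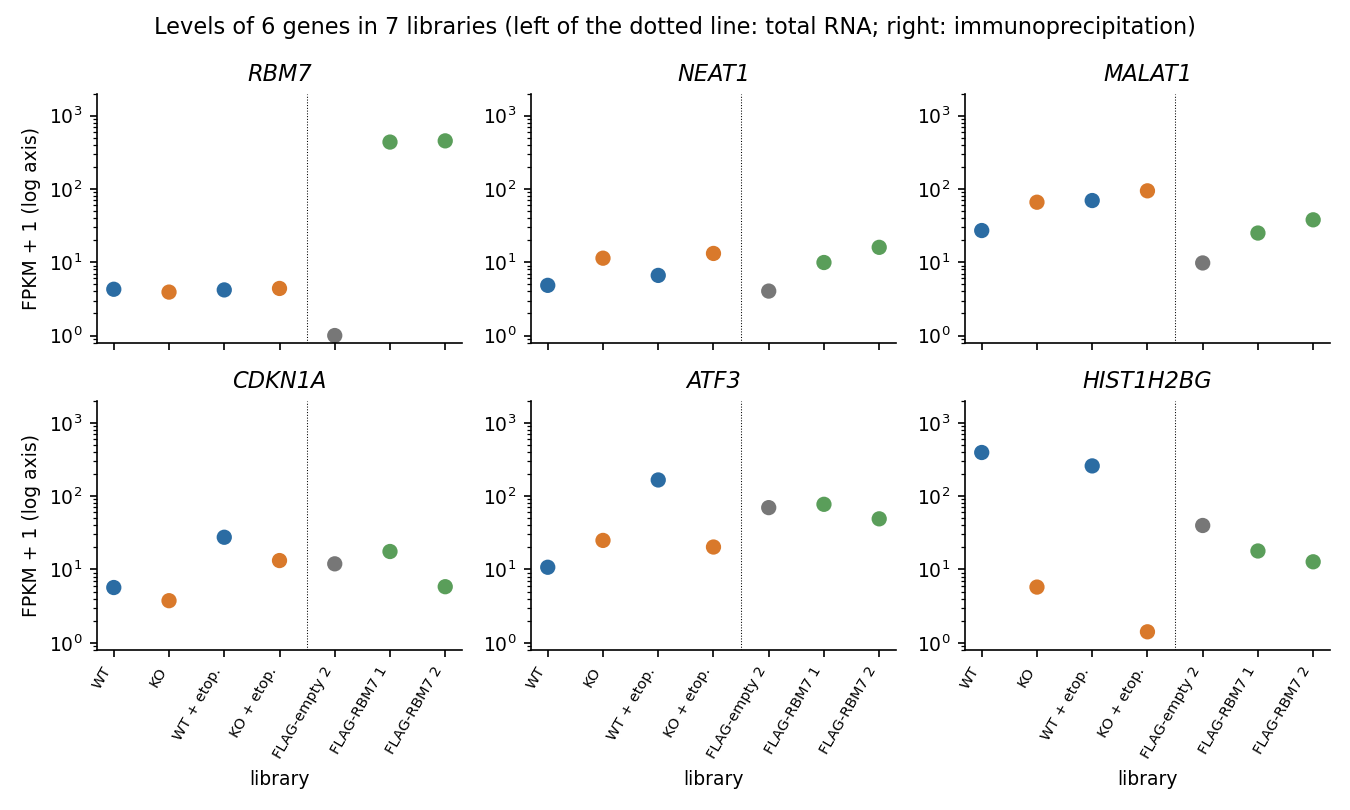
FPKM plus 1 on a log axis for 6 genes, a point per library; FLAG-empty replicate 1 is left out because most of its values are missing. RBM7 stays between 2.92 and 3.39 FPKM in the 4 total RNA libraries, and HIST1H2BG falls from 392.3 FPKM in wild type to 4.75 FPKM in the untreated library labelled knockout.

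The immunoprecipitation asked which RNAs are recovered with FLAG-RBM7. No total RNA library of the FLAG-empty or FLAG-RBM7 cells was in the series, so a fold cannot separate recovery from abundance. For RBM7 it may include message of the FLAG-RBM7 construct itself. Besides RBM7 (log2 fold change 8.79, SE 0.918, adjusted p = 5.75e-18), the nuclear long noncoding RNAs MALAT1 and NEAT1 were higher with FLAG-RBM7. The size of the RBM7 value is set by the pseudocount over a single near-zero control (12.10 with a pseudocount of 0.1 and 6.48 with 5), and its spread is the limma trend over all genes, not its own. MALAT1, a nuclear speckle RNA, reached 30.4 ± 9.10 FPKM with FLAG-RBM7 and 5.21 ± 5.04 FPKM with FLAG-empty (SD, n = 2 each, log2 fold change 2.60, adjusted p = 0.00131). NEAT1, the scaffold of paraspeckles, reached 11.9 ± 4.28 FPKM against 2.15 ± 1.26 FPKM (log2 fold change 2.06, adjusted p = 0.00515). Both lie on chromosome 11, NEAT1 from 65422774 to 65445540 and MALAT1 from 65497688 to 65506516 in hg38. Neither call held when any library was left out, with adjusted p from 0.184 to 0.598 for NEAT1 and from 0.0882 to 0.635 for MALAT1, while the log2 fold changes stayed positive, from 1.64 to 2.48 for NEAT1 and from 1.65 to 3.54 for MALAT1.

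Other RNAs higher with FLAG-RBM7 were those of AFMID, an enzyme of tryptophan breakdown (4.17), DAP, a death-associated protein (3.25), PITPNB, a phosphatidylinositol transfer protein (2.92), SLC29A2, a nucleoside transporter (2.56), TUBB4A, a tubulin (2.54), and the antisense RNA ENO1-AS1 (2.5). For these 6 the only control value lay at 0.0156 FPKM or less, so their folds depend on the pseudocount. RNAs lower with FLAG-RBM7 included NME1-NME2, a readthrough of neighbouring kinase genes (-4.79), DCXR, a sugar reductase (-3.89), ZYX, a focal adhesion protein (-3.87), ALDH4A1, of proline breakdown (-3.65), and SPHK1, the sphingosine kinase (-3.64). DCXR rested on 1 library, with 137.9 FPKM in FLAG-RBM7 replicate 1 and 0.0395 FPKM in replicate 2. GHET1 (-6.52), GAS5-AS1 (-5.35) and the testis histone HIST1H1T (-4.11) rested on FLAG-empty replicate 1, which listed them at 12261, 881.6 and 2981 FPKM.

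In all, limma called 205 of 9817 genes, 39 higher and 166 lower, beside a median log2 fold change of -0.53 over all genes. Of the 39 higher genes, 23 lay under 0.01 FPKM in FLAG-empty replicate 2, and 3 had a value in all 4 libraries, as did 21 of the 166 lower genes. For all other calls FLAG-empty was a single library, assumed to vary like FLAG-RBM7, and limma took the spread from its trend over all genes, not from the gene itself. The count depended on the scaling: centring the libraries gave 438 genes with 64.6% higher, against 19% as deposited, and moved the all-gene median to -0.01. Quantile normalization gave 6 genes, all higher, and rescaling without short RNAs gave 1, RBM7, at an all-gene median of 0.21. With the zeros of FLAG-empty replicate 1 kept, limma called 0 of 9386 genes, with 13 at an unadjusted p under 0.05, at an all-gene median of 1.17.

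**Figure D2:**
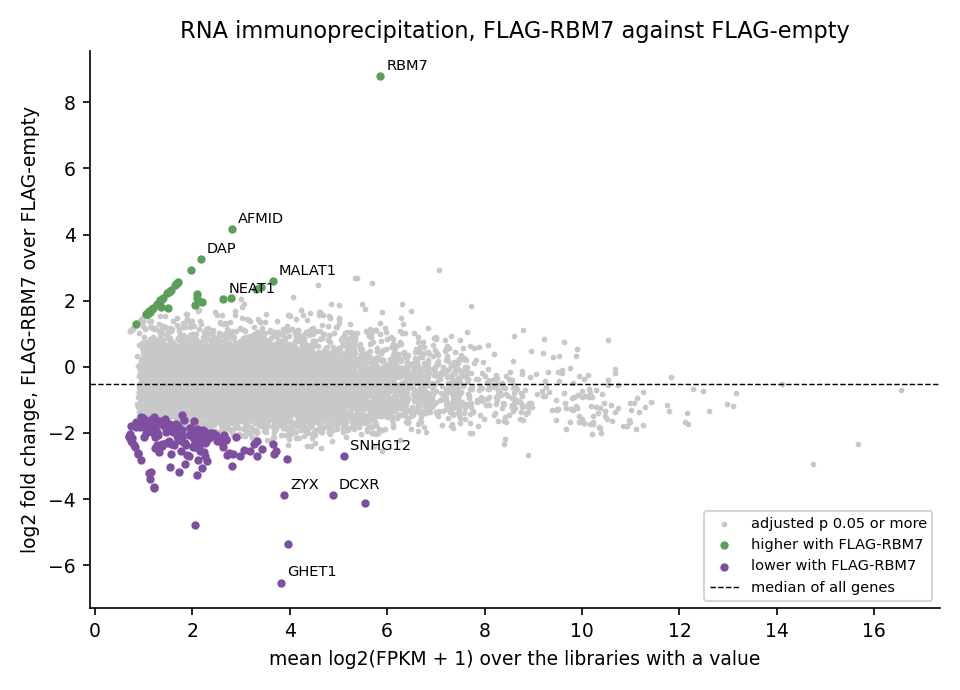
Log2 fold change of FLAG-RBM7 over FLAG-empty against the mean log2(FPKM + 1) over the libraries with a value, a point per gene. The dashed line is the median of all genes at -0.53, and MALAT1 (2.60) and NEAT1 (2.06) lie among the higher genes.

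Several fixed gene lists stood apart from the rest of the immunoprecipitated RNA. The snoRNA host genes, whose introns carry small nucleolar RNAs, were lower with FLAG-RBM7: all 8 had negative values with a median of -1.47, 2 fell over all genes tested and 5 fell adjusted over the list alone, among them SNHG12 (-2.71) and SNHG19 (-2.70). Their camera adjusted p was 4.78e-04, and adjusted p = 0.995 with an estimated correlation. Here and below, the test with an estimated correlation had 1 residual degree of freedom and could hardly call any list. It therefore does not tell how much correlation between genes matters. Antisense RNAs and intergenic long noncoding RNAs ranked above other genes, which the test sets beside an all-gene median of -0.53, so that lists with a negative median and mean can rank up (camera adjusted p = 0.00527 and 0.00967, each with adjusted p = 0.995 with an estimated correlation). With the zeros of FLAG-empty replicate 1 kept, both turned to rank below other genes (adjusted p = 2.04e-12 and 2.26e-14), and the antisense list also turned, without a call, at a mean of at least 5 FPKM (adjusted p = 0.732). The antisense median was -0.08 as deposited and 0.44 when centred, with 4 higher and 5 lower of 142 (6 and 6 adjusted over the list alone), MED4-AS1 (2.2) and DNAJC9-AS1 (-2.37) among them. The intergenic median was -0.10 as deposited and 0.40 when centred, with 0 higher and 1 lower of 50 (3 and 4 adjusted over the list alone). Read strand was not given in the sources used here, so values of antisense RNAs may hold reads of the opposite gene.

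The paraspeckle proteins, partners of NEAT1, also ranked above other genes (camera adjusted p = 0.0124, and adjusted p = 0.995 with an estimated correlation). The median of -0.18 and the mean of 0.04 over their 18 measured members differ in sign. The NEXT and nuclear exosome list was called as well (adjusted p = 0.0105, and adjusted p = 0.995 with an estimated correlation), with a median of -0.27, a mean of 0.14 and RBM7 itself as the only called gene of 23, 1 adjusted over the list alone. Its call was lost when centred (adjusted p = 0.0668). In the nuclear long noncoding RNA list, MALAT1 and NEAT1 were 2 higher of 10, also 2 adjusted over the list alone, and the list did not pass (median -0.57, adjusted p = 0.163).

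Replication-dependent histone messages, which end in a stem-loop in place of a poly(A) tail, had negative values in 41 of 42 genes (median -1.53), yet 0 were called, 0 adjusted over the list alone, and the list did not pass as deposited (camera adjusted p = 0.243). Under the 3 other scalings it passed as lower (adjusted p = 7.83e-06 when centred), while with the zeros of FLAG-empty replicate 1 kept its median turned to 3.96. Cytosolic ribosomal protein messages were negative in 76 of 76 genes (median -0.95, 0 called, 0 adjusted over the list alone, adjusted p = 0.998), against 3.97 with those zeros kept. The 20 lists without a call had adjusted p from 0.128 to 0.998. Among their members RPTOR, the mTORC1 subunit (-3.29), DDIT3, a stress transcription factor (-2.32), and CASP9, the initiator caspase (-2.35), were lower, and MAD1L1, a spindle checkpoint gene (2.08), was higher.

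The next comparison asked what separates the libraries labelled knockout from wild type, averaged over both treatments. Highest in the libraries labelled knockout were MAGEB2, a melanoma antigen gene on the X chromosome (log2 fold change 3.97, SE 0.187), TMEM107, a ciliary transition zone protein (2.94), TMSB15A, a thymosin (2.90), and the connective tissue growth factor CTGF (2.84), followed by ANKRD1 (2.25), which like CTGF and CYR61 (1.56) is a target of the YAP coactivator. The lowest were the histone genes HIST1H2BG (-6.81) and HIST1H2AE (-5.33), the epithelial keratin KRT8 (-2.84), FAM84B (-2.52) and SAT1, the polyamine acetyltransferase (-1.93). AFMID (-2.01) and VCPKMT (-1.84) were called lower because of near-zero values in the etoposide library labelled knockout, at 0.000338 and 4.54e-05 FPKM. NEAT1 was higher, at 10.4 and 12.2 FPKM against 3.84 and 5.61 FPKM in wild type (1.11, SE 0.163, adjusted p = 0.00879), and so was MALAT1 (0.86, SE 0.184, adjusted p = 0.0245). Both lost their calls when the libraries were centred (adjusted p = 0.0576 and 0.0798), at log2 fold changes of 1.14 and 0.89.

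The limma fit called 1440 of 10818 genes, 715 higher and 725 lower in the libraries labelled knockout. With 1 library per group, the spread came from how the genotype difference changed between treatments. When the libraries were centred, 6 genes were called, namely MAGEB2, TMEM107 and TMSB15A higher and HIST1H2BG, HIST1H2AE and KRT8 lower, with 2910 at an unadjusted p under 0.05. Rescaling without short RNAs gave 1445 genes with 70.9% higher, against 49.7% as deposited, and moved the all-gene median from -0.01 to 0.12.

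Antisense, intergenic and nuclear long noncoding RNAs ranked higher as lists in the libraries labelled knockout, although most members did not pass and noncoding snoRNA hosts fell. Of 166 antisense RNAs, 36 rose and 3 fell (46 and 5 adjusted over the list alone), with a median of 0.28 and the examples HEXA-AS1 (1.61), IDH1-AS1 (1.48), IPO9-AS1 (1.42) and CRTC3-AS1 (1.42). Of 53 intergenic long noncoding RNAs, 13 rose and 0 fell (16 and 1 adjusted over the list alone), with a median of 0.38 and LINC02076 (1.56), LINC01465 (1.46) and LINC00472 (1.23) among them. Camera gave adjusted p = 1.9e-06 for the antisense list and 5.16e-05 for the intergenic list, and adjusted p = 0.603 for each with an estimated correlation. Of 12 nuclear long noncoding RNAs, NEAT1, MALAT1 and the telomerase RNA TERC (0.81) rose (3 higher and 1 lower adjusted over the list alone, median 0.29, adjusted p = 0.0313, and adjusted p = 0.603 with an estimated correlation). That call was lost under quantile normalization (adjusted p = 0.063). Host genes of microRNAs were higher too, with 2 of 6 called, MIR181A1HG (1.67) and MIR497HG (0.79), 4 adjusted over the list alone (median 0.70, adjusted p = 0.00513, and adjusted p = 0.603 with an estimated correlation). The minor spliceosome RNAs RNU11 (1.35) and RNU12 (1.25), the Cajal body RNA SCARNA9 (0.69) and the primate RNA BCYRN1 (0.88) rose as well, in lists too short to test.

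Messages of ribosomal proteins, mitosis genes, snoRNA hosts and p53 targets ranked lower in the libraries labelled knockout, although most members of the first, second and last of these lists did not pass. Of 76 cytosolic ribosomal protein genes, 22 fell (33 adjusted over the list alone), including RPS24 (-1.55), RPL17 (-1.17) and RPL7A (-1.02), with a median of -0.38 (adjusted p = 4.31e-13, and adjusted p = 0.603 with an estimated correlation). Of 28 mitosis genes, 6 fell (12 adjusted over the list alone), among them the kinesins KIF20A (-0.95) and KIF11 (-0.92) and the proliferation marker MKI67 (-0.93), with a median of -0.32 (adjusted p = 5.86e-05, and adjusted p = 0.736 with an estimated correlation). The mitosis median was -0.14 at percentile 6.09 in the untreated pair and -0.47 at percentile 0 in the etoposide pair. The snoRNA host genes SNHG15 (-1.38), SNHG7 (-1.04), EPB41L4A-AS1 (-1.0) and ZFAS1 (-0.83) were among 5 of 8 that fell (1 higher and 5 lower adjusted over the list alone, median -0.72, adjusted p = 0.00513, and adjusted p = 0.603 with an estimated correlation). Targets of p53 were lower, with 5 of 25 called (1 higher and 7 lower adjusted over the list alone), including the cell cycle inhibitor CDKN1A (-0.83) and the kinase PLK2 (-1.17), with a median of -0.32 (adjusted p = 0.00513, and adjusted p = 0.738 with an estimated correlation). This came from the etoposide pair, where the p53 median was -0.48 at percentile 0.01, while the untreated median was -0.06 at percentile 14.57 and ran from -0.223 to 0.003 over the settings. Genes of DNA replication and S phase were not lower, with 0 of 28 called, 0 adjusted over the list alone (median 0.06, adjusted p = 0.166).

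Of 24 genes of NEXT and the nuclear exosome, the core subunits EXOSC1 (-0.89), EXOSC2 (-0.89), EXOSC8 (-0.62) and EXOSC5 (-0.50) fell, also 4 adjusted over the list alone (median -0.18, adjusted p = 0.021, and adjusted p = 0.603 with an estimated correlation). That call was lost once the median of 51 neighbouring genes was removed (adjusted p = 0.109). Histone genes were lower on average, with 4 of 43 called, 4 adjusted over the list alone (median -0.40, adjusted p = 1.1e-04, and adjusted p = 0.751 with an estimated correlation), but the untreated pair had a median of 0.12 and the etoposide pair of -1.05. Very long genes were higher, with KANSL1 (0.70) the only 1 called of 32, 0 adjusted over the list alone (median 0.33, adjusted p = 0.0195, and adjusted p = 0.603 with an estimated correlation). In a first run on raw t statistics this list did not pass (adjusted p = 0.0516). The signs of these 11 list medians held under every scaling tried.

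The other 14 lists had adjusted p from 0.13 to 0.979, although some members were called. The interferon-induced membrane genes IFITM3 (1.39) and IFITM2 (1.09), the small heat shock protein HSPB1 (1.28), the chaperone PDIA4 (1.06), the DNA break sensor PARP1 (0.70) and the matrix protein SPARC (0.63) rose. The cochaperone BAG3 (-0.89) and the paraspeckle protein PSPC1 (-0.83) fell.

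Genotype differences also followed chromosomes or parts of them. Of 404 genes on chromosome 10, 38.6% were called lower in the libraries labelled knockout and 2.0% higher, and of 1182 genes on chromosome 1, 27.9% were called higher and 2.1% lower. Chromosome medians ran from -0.47 on chromosome 10 to 0.31 on chromosome 1. The 101 genes of chromosome 10 from 102132994 to 133424572 had medians of -0.676 untreated and -0.805 with etoposide. The values of single genes named above keep such offsets, so examples from shifted regions may owe part of their difference to them. With the median of each chromosome removed 645 genes were called, 535 of them among the 1440, and with the median of 51 neighbouring genes removed 282 were called, 258 of them among the 1440. The mitosis and ribosomal protein lists passed in all 13 settings at the preset correlation, these removals among them.

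**Figure D3:**
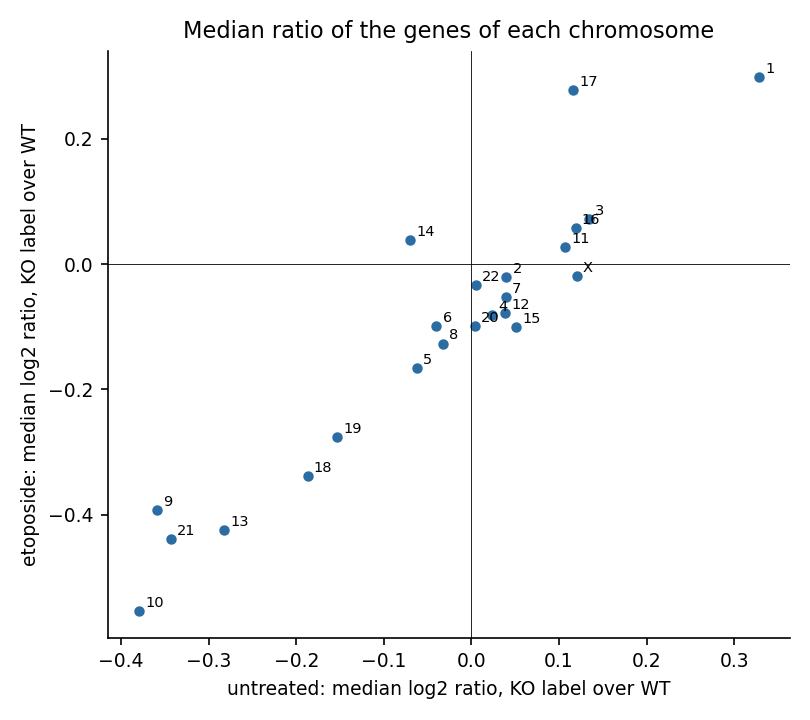
Median log2 ratio of the library labelled knockout over wild type for the genes of each of 23 chromosomes, untreated on the horizontal axis and with etoposide on the vertical axis. Chromosomes 9, 10, 13 and 21 lie low and chromosome 1 lies high in both pairs (Pearson r = 0.938 across chromosomes).

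Etoposide, averaged over both genotype labels, raised CDKN1A, the cell cycle inhibitor induced by p53, and lowered most histone messages. The highest were SERTAD1, an E2F cofactor (log2 fold change 2.1, SE 0.306), CDKN1A (2.05, SE 0.173), the transcription factor HES6 (1.91), HEXIM1, an inhibitor of the elongation factor P-TEFb (1.76), PHLDA3, a p53-induced repressor of AKT (1.69), FAM46C (1.62), RGS2 (1.57) and GADD45B (1.55). The lowest were linker and core histones, HIST1H1D (-4.57, SE 0.398), HIST1H3J (-3.68), HIST1H3H (-2.68), HIST1H2BJ (-2.64), HIST1H1C (-2.59), HIST1H1E (-2.51), HIST1H4B (-2.48) and HIST1H3A (-2.39). MALAT1 rose (0.94, adjusted p = 0.0259), while NEAT1 (0.33, adjusted p = 0.228) and RBM7 (0.07, adjusted p = 0.852) did not pass. The MALAT1 call was lost when the libraries were centred (limma adjusted p = 0.0923) and after quantile normalization (0.0693). It was also lost without the trend (0.0959) and in the robust fit (0.118), at log2 fold changes from 0.91 to 0.94 in these settings.

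The limma fit called 955 of 10818 genes, 367 higher and 588 lower with etoposide. When the libraries were centred only HIST1H3J was called, with 2655 genes at an unadjusted p under 0.05. The share of higher genes was 38.4% as deposited, 28% after quantile normalization (418 genes) and 76.6% after rescaling without short RNAs (1533 genes), which moved the all-gene median from 0.02 to 0.19. Without the variance trend, 98 genes were called, 13.3% of them higher.

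Of 43 replication-dependent histone genes, 37 fell and 1 rose (38 and 1 adjusted over the list alone), with a median of -1.91 (adjusted p = 7.78e-28, and adjusted p = 0.792 with an estimated correlation). Genes of DNA replication and S phase moved the other way: 11 of 28 rose (20 higher and 1 lower adjusted over the list alone), including the G1/S regulators CCNE2 (1.05) and E2F1 (0.94), the ribonucleotide reductase subunit RRM2 (0.89) and the origin licensing factor CDC6 (0.82), with a median of 0.36 (adjusted p = 5.68e-10, and adjusted p = 0.792 with an estimated correlation). Of 28 mitosis genes 13 fell (16 adjusted over the list alone), among them the kinase PLK1 (-1.48), HMMR (-1.37) and CDC20, the activator of the anaphase-promoting complex (-1.01), with a median of -0.50 (adjusted p = 1.25e-10, and adjusted p = 0.792 with an estimated correlation). Of 25 p53 targets 6 rose and 0 fell (16 and 0 adjusted over the list alone), CDKN1A, PHLDA3 and PLK2 (1.22) among them, with a median of 0.56 (adjusted p = 1.53e-07, and adjusted p = 0.792 with an estimated correlation).

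Very long genes fell in 15 of 32 cases (21 adjusted over the list alone), with a median of -0.67 and the examples PARD3, a cell polarity gene (-1.78), CDKAL1 (-1.53) and RPTOR (-1.32) (adjusted p = 3.92e-11, and adjusted p = 0.792 with an estimated correlation). Zinc finger genes ranked higher as a list (median 0.25, adjusted p = 3.57e-05, and adjusted p = 0.792 with an estimated correlation), with 3 higher and 2 lower of 372, 0 adjusted over the list alone. The snoRNA host genes SNHG12 (1.52), ZFAS1 (0.61) and SNHG15 (0.61) were the 3 of 8 that rose (5 adjusted over the list alone, median 0.45, adjusted p = 0.00509, and adjusted p = 0.792 with an estimated correlation). The signs of these list medians held under every scaling tried.

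A further 3 lists were called near the threshold, each with adjusted p = 0.792 with an estimated correlation. In the interferon list (median 0.28, adjusted p = 0.0237) ISG15 rose (0.96), 1 of 10 and 1 adjusted over the list alone. The microRNA and snoRNA host genes (median 0.41, adjusted p = 0.0481) had 2 of 14 higher, with 6 higher and 1 lower adjusted over the list alone, and passed in 7 of 11 settings at the preset correlation, with a median of 0.03 and adjusted p = 0.312 without an expression filter. The immediate early genes (median 0.62, adjusted p = 0.0481) had 4 higher, JUNB (1.51) and IER2 (1.41) among them, and the growth regulator MYC lower (-1.63), of 13 genes (5 and 1 adjusted over the list alone), and passed in 6 of 11 such settings, with adjusted p = 0.473 after rescaling without short RNAs. In a first run on raw t statistics neither the interferon list (adjusted p = 0.0585) nor the immediate early list (adjusted p = 0.087) passed. The remaining 15 lists had adjusted p from 0.194 to 0.938. Homologous recombination and DNA damage signalling was among them, with 2 higher and 1 lower of 30 (3 and 3 adjusted over the list alone, median 0.11, adjusted p = 0.396). Among their members NFKBIA, the inhibitor of NF-kappaB (1.45), PARP2 (0.91), the noncoding RNA NORAD (0.60) and the chaperone DNAJB1 (0.57) rose, and the inducible chaperones HSPA1A (-1.06) and HSPA1B (-1.05) and the exosome helicase SKIV2L2 (-0.61) fell. Cytosolic ribosomal protein genes had a median of -0.005 as deposited, with 1 of 76 called and 0 adjusted over the list alone, and 0.37 after quantile normalization.

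The single pairs have no replicates, so their ratios carry no test across genes, and the place of a list among 10000 random lists of like expression is a description only. With etoposide in wild type, ATF3, a stress transcription factor, had the highest ratio (log2 ratio 3.96, from 9.71 to 165 FPKM), followed by GADD45A (3.04), SERTAD1 (2.86) and the growth factor HBEGF (2.68), and HIST1H1D (-3.50), HIST1H3J (-3.49), HIST1H3H (-2.08) and the axon guidance receptor ROBO1 (-2.06) had the lowest. With etoposide in the line labelled knockout, TGIF2 (2.14), RBM14-RBM4 (2.07), CDKN1A (1.82) and HES6 (1.55) had the highest ratios, and HIST1H1D (-5.63), HIST1H3J (-3.88), HIST1H1C (-3.37) and HIST1H4B (-3.32) the lowest. At least 2-fold ratios were counted in 229 genes up and 224 down in wild type, and in 63 up and 330 down in the line labelled knockout. The selection of transcripts on the untreated library labelled knockout limits ratios above 1 against that library, and among 7386 genes with a mean of 5 FPKM or more the counts were 128 and 134 in wild type and 37 and 159 in the line labelled knockout. The share of higher genes was 50.6% in wild type as deposited, 36.8% centred and 70.3% rescaled without short RNAs. In the line labelled knockout it was 16% as deposited, 28.6% after quantile normalization and 40.6% rescaled.

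**Figure D4:**
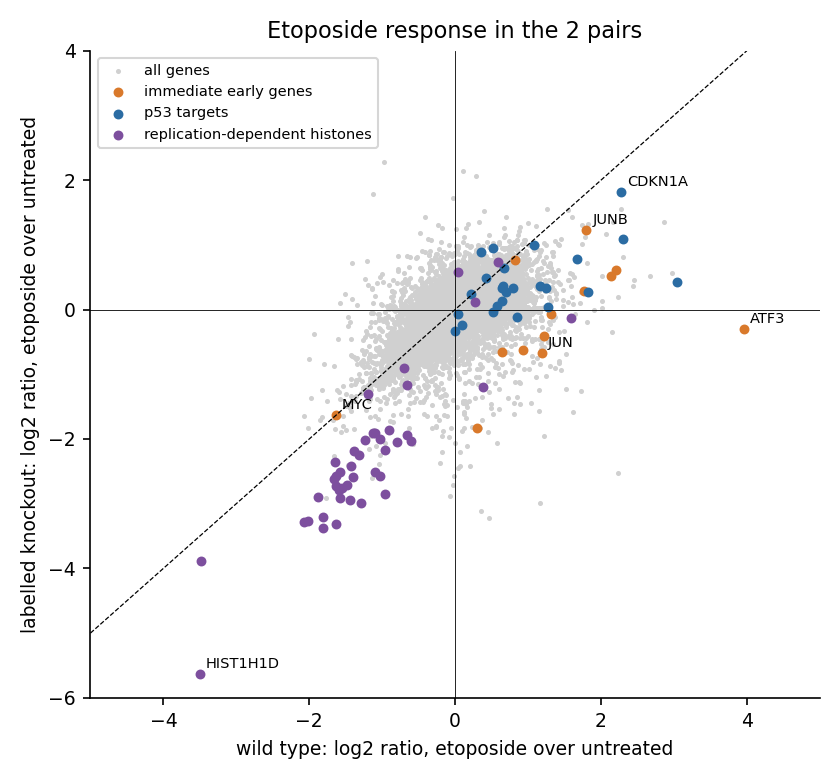
Log2 ratio of etoposide over untreated in the line labelled knockout against that in wild type, a point per gene, with the line of equal response dashed. Immediate early genes have a median of 1.22 in wild type and -0.30 in the line labelled knockout, and the histone median is lower in the line labelled knockout (-2.51) than in wild type (-1.32).

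Responses of the 2 lines ran in parallel over all genes (Pearson r = 0.542 and Spearman rho = 0.55 across 10818 genes, which are not independent replicates), with 121 genes at least 2-fold lower in both against 6.8 if independent, 23 at least 2-fold higher in both against 1.3, and 12 opposite. The immediate early genes were the list with the widest gap. Their median was 1.22 in wild type, above all random lists, and -0.30 in the line labelled knockout, at percentile 0.78, with a difference of -1.56 at percentile 0. In the untreated library labelled knockout the list already lay above wild type (median 0.43, percentile 99.91). Of its 13 genes, 5 were at least 2-fold higher there. Only 14 of the 26 list members were listed, and the cut on that untreated library favours members high in it. With etoposide the list lay below wild type (-0.92, percentile 0). JUN, a subunit of the AP-1 factor, went from 72.2 to 165.4 FPKM in wild type and from 161 to 100.7 FPKM in the line labelled knockout, and ATF3 from 9.71 to 165 FPKM and from 23.9 to 19.2 FPKM. MYC had like ratios in both, -1.64 and -1.63. The p53 targets had a median of 0.67 in wild type and 0.33 in the line labelled knockout, zinc finger genes 0.40 and 0.07, and histones -1.32 and -2.51. Under every setting tried the immediate early median stayed between 0.73 and 1.64 in wild type and between -0.36 and -0.08 in the line labelled knockout.

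For the interaction, the difference of the log2 ratios was highest for TGIF2 (2.03), BLOC1S5 (1.96), RCOR3 (1.84) and RBM14-RBM4 (1.78) and lowest for ATF3 (-4.25), MVK, the mevalonate kinase (-3.46), ANKRD1 (-3.18) and AFMID (-2.81). MVK and AFMID rested on values of 0.0231 and 0.000338 FPKM in the etoposide library labelled knockout. It was at least 2-fold up in 94 genes and down in 336, a share of 21.9% up as deposited, 36% centred and 36.8% after quantile normalization.

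The pairs of the library labelled knockout over wild type also ran in parallel (Pearson r = 0.579 and Spearman rho = 0.585 across 10818 genes, not independent replicates), with 81 genes at least 2-fold higher in both against 5.3 if independent, 59 lower in both against 3.4, and 12 opposite. Without treatment, MAGEB2 (4.05), CTGF (3.90), ANKRD1 (3.84) and TMEM107 (2.93) had the highest ratios and HIST1H2BG (-6.10), HIST1H2AE (-4.54), FAM84B (-2.75) and KRT8 (-2.58) the lowest. With etoposide, MAGEB2 (3.89), TMEM107 (2.95), TMSB15A (2.91) and TNFSF13 (2.35) were highest and HIST1H2BG (-7.52), HIST1H2AE (-6.12), AFMID (-3.41) and MVK (-3.14) lowest. Antisense RNAs had a median of 0.29 untreated and 0.36 with etoposide and intergenic long noncoding RNAs 0.38 and 0.44, at percentiles from 99.99 to 100. Without an expression filter the untreated percentile was 93.66 for antisense RNAs and 36.24 for intergenic long noncoding RNAs. At least 2-fold ratios were counted in 231 genes up and 105 down untreated, and in 249 up and 353 down with etoposide. The selection of transcripts favours ratios above 1 in the untreated pair, and among the 7386 genes with a mean of 5 FPKM or more the counts were 92 and 70 untreated and 112 and 203 with etoposide. The share of higher genes was 68.8% untreated as deposited, 57.1% after quantile normalization and 83.5% rescaled. With etoposide it was 41.4% as deposited, 57.2% centred and 60.2% rescaled.

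RNAs recovered with FLAG-RBM7 were then followed in the libraries labelled knockout, since targets of a decay adaptor would accumulate without it. Of the 36 genes higher with FLAG-RBM7 and measured in both sets, 7 (19.4%) were at least 2-fold higher in the untreated library labelled knockout against 2.1% of all genes, and their median log2 ratio was 0.20, at percentile 94.93 of 10000 random lists. With etoposide 1 (2.8%) was at least 2-fold higher, and the median was -0.02, at percentile 52.27. The 160 genes lower with FLAG-RBM7 had 10 (6.2%) at least 2-fold higher and a median of 0.12 at percentile 95.35 untreated, and 12 (7.5%) and a median of 0.05 at percentile 97.67 with etoposide. The difference between the 2 sets was not tested. The share of 2.1% covers all genes and was not matched on expression. For etoposide over untreated in wild type, where the genotype label is the same, 5 (13.9%) of the 36 were at least 2-fold higher, also against 2.1% of all genes. An excess of 2-fold ratios in these genes was thus not particular to the knockout label. When the libraries were centred, 278 genes were followed, with a median of 0.03 at percentile 98.01 untreated and -0.03 at percentile 0.21 with etoposide. Under settings that called fewer than 20 genes higher, where up to 200 with the lowest p were taken, the etoposide median ran from -0.17 at percentile 0.13 (a mean of at least 5 FPKM, 167 genes) to 0.44 at percentile 100 (only genes above 0 in every library, 79 genes), so no direction is drawn for that pair.

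**Figure D5:**
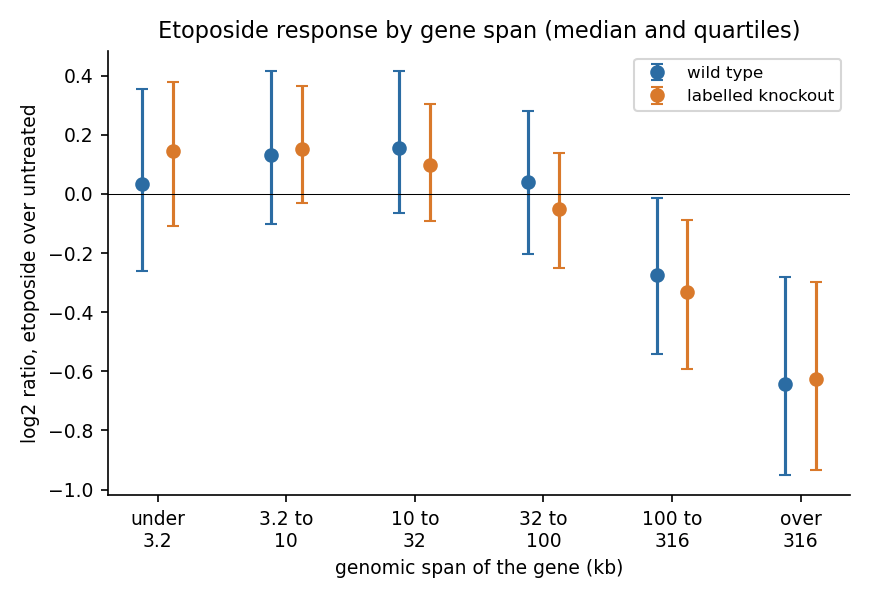
Log2 ratio of etoposide over untreated by the genomic span of the gene, in 6 span classes, as median and quartiles for wild type and the line labelled knockout. The longest class has a median of -0.64 in wild type and -0.63 in the line labelled knockout, over 277 genes.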

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

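All tests of row selection, library scaling, raised levels and weaker responses in this part were chosen only after the result was seen; for the lasting difference only the chromosome medians averaged over both pairs had been seen.

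Of the 264 genes that the naming rule selects, 7 moved in opposite directions with etoposide in the 2 lines, by at least 1.5-fold in each, which is what picked them; each line has 1 library per treatment, and the difference was not tested. The difference of the log2 ratios, line labelled knockout minus wild type, was -4.152 for DDIT3 (1.16 in wild type and -2.992 in the line labelled knockout), -3.177 for ANKRD1 (1.216 and -1.961), -2.385 for ZYX (1.451 and -0.934) and -2.346 for VCPKMT (0.893 and -1.453). It was -2.148 for NME1-NME2 (1.112 and -1.036), -1.299 for CYR61 (0.641 and -0.658) and 1.955 for BLOC1S5 (-1.205 and 0.75). JUN, which the rule did not select, also passed that limit (1.186 and -0.672), and genes such as ATF3 (3.955 and -0.299) were opposite but under the limit in 1 line. DDIT3 and VCPKMT rest on near-zero values in the etoposide library labelled knockout. Among all 10818 genes, 62 were opposite at 1.5-fold or more, 52 of them up in wild type and down in the line labelled knockout.

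Antisense and intergenic noncoding RNAs ranked higher in the libraries labelled knockout. Selection of transcripts on the untreated library labelled knockout did not cut the antisense list, of which 175 of 360 listed members lay under 1 FPKM there. Of the measured members, however, only 8 of 166 did, and 1 of 53 for intergenic RNAs. Without an expression filter the untreated percentile was 93.66 for antisense and 36.24 for intergenic RNAs, so selection is not excluded. The antisense median with etoposide lay at percentile 100, a description only, as the same line is compared. Chromosome-wide offsets are not the likely source, as the antisense median was 0.324 after the median of neighbouring genes was removed. Reads of the listed sense transcripts are not the likely source, because in 134 pairs the sense genes had a median of 0.005 against 0.278 for the antisense RNAs (permutation p = 1e-05, the smallest possible). The Pearson r of antisense and sense values across these pairs was 0.252. Sense reads outside the listed transcripts are not excluded, since their level and the read strand are unknown. The rise may reflect weaker nuclear decay or another lasting difference between the lines, which these libraries cannot tell apart, since RBM7 RNA did not fall.

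Genes of the same chromosome differed together between the libraries labelled knockout and wild type, often over only part of the chromosome. A factor per library cannot give this, as shuffled genes never reached the observed share of variance between chromosomes, 18.43% (permutation p = 1e-05, the smallest possible, genes not independent). Gene span does not explain it, since removing it shrank the range of chromosome medians by -2.1%, that is, widened it. The offsets repeated in the etoposide pair, whose libraries are separate (Pearson r = 0.938 across 23 chromosomes), which is consistent with a lasting difference between the cell populations such as DNA copy number. DNA was not measured, and such a difference may lie behind part of the 1440 genotype calls.

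The immediate early list had a median of 1.22 after etoposide in wild type and -0.30 in the line labelled knockout. In the latter, 5 of 13 members still had positive ratios, and the percentile of the median ran from 0.16 to 18.83 over the settings. Of the 26 members, 14 were listed and 13 measured. The cut of the listing on the untreated library labelled knockout favours members high there, and its part in this pattern was not tested. A raised level before treatment was seen (median 0.431, percentile 99.91) and is part of the difference. As the whole cause it would leave like levels under etoposide, where the list had a median of -0.92 at percentile 0. CTGF (1.774) and CYR61 (0.914) nevertheless stayed higher there. The slope of 0.534 over all genes came with a Pearson r of 0.542, so scatter between the lines lowers it, and it cannot tell whether responses were weaker. Among 7386 genes with a mean of 5 FPKM or more, 37 were at least 2-fold higher with etoposide in the line labelled knockout against 128 in wild type. At least 2-fold lower were 159 against 134. A generally weaker response would not give the slope of 1.418 over histone and S phase genes. Slopes of 0.329 for p53 targets and 0.406 for the immediate early genes leave a weaker response of these induced genes open. Not every list that rose weakened. In wild type and the line labelled knockout, medians were 0.354 and 0.399 for DNA replication and S phase genes, with a median difference per gene of 0.04 at percentile 70.02. The snoRNA host genes rose in both, with medians of 0.545 and 0.444, but their median difference per gene was -0.211 at percentile 1.6. Zinc finger genes had 0.402 and 0.07. With 1 library each, a difference in the timing or handling of a single culture may give the same picture and was not tested.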

How the results depend on the processing

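Keeping zeros, removing chromosome or neighbour medians, leaving out genes under 0.01 FPKM and leaving out RBM7 were chosen only after the result was seen. The cause of the changes below was not tested unless stated. Of all values, 4994 were the same under the alternatives, 655 weaker, 137 stronger, 137 moved and 9 reversed. Depth is unknown, so what it limits cannot be given.

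In the immunoprecipitation, the 205 calls became 136 with a pseudocount of 0.1, 24 at a mean of at least 5 FPKM, 438 when centred, 6 after quantile normalization, 1 after rescaling without short RNAs, 0 with only genes above 0 in every library (61 at an unadjusted p under 0.05 in limma; 332 genes remain), 130 without genes under 0.01 FPKM, 135 without the trend and 14 with a replicate block (345 genes remain). The replicate differences of the 2 arms had a correlation of 0.176 over 345 genes; with 2 pairs only, the replicate numbers were not taken as pairs. Leaving out 1 library gave 0 to 181 calls and 0 to 5 lists, assuming that a lone library varies like the other arm, over 9791 genes and 25 lists without FLAG-empty replicate 1 but over only 335 to 360 genes and 6 lists without any other library; leaving out FLAG-RBM7 replicate 1 (45 at an unadjusted p under 0.05 in limma) or 2 (25) left 0. With zeros kept, 0 genes (13 at an unadjusted p under 0.05 in limma) and 9 lists were called, against 5 lists. Called lists numbered 2 with only genes above 0 in every library and 3 with a replicate block, each of 6 that could be tested, and 0 of 25 with an estimated correlation. The direction of lists relative to all other genes reversed as follows, with the list median. Antisense RNAs reversed at a mean of at least 5 FPKM (-0.443) and without FLAG-empty replicate 2 (-0.416), and leaving out 1 library gave medians from -0.473 to -0.002. Ribosomal proteins reversed when centred (-0.435) and when rescaled (-0.079). With zeros kept, histones (3.956), nuclear long noncoding RNAs (-0.124), microRNA host genes (0.484), antisense RNAs (0.155) and intergenic long noncoding RNAs (0.023) reversed, beside an all-gene median of 1.17.

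For genotype, the 1440 calls became 6 when centred, 884 after quantile normalization, 253 without the trend, 645 after chromosome medians and 282 after 51 neighbours were removed. For etoposide, the 955 calls became 1 when centred, 418 after quantile normalization, 1533 when rescaled, 550 with the highest transcript of a symbol and 98 without the trend. With an estimated correlation, 0 of the 11 genotype lists and 0 of the 10 etoposide lists were called.

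Counts of 2-fold genes in the pairs were 336 for the library labelled knockout over wild type untreated, 602 with etoposide, 453 for etoposide in wild type, 393 in the line labelled knockout and 430 for the interaction. In that order, they were 650, 1026, 889, 724 and 751 with a pseudocount of 0.1, 66, 156, 112, 104 and 100 with a pseudocount of 5, 162, 315, 262, 196 and 173 at a mean of at least 5 FPKM, and 649, 989, 826, 682 and 708 when rescaled. A larger pseudocount shrinks ratios and a stricter filter tests fewer genes by construction. The untreated median of genes higher with FLAG-RBM7, 0.197 over the called genes, was 0.031 over the called genes when centred. Elsewhere the measured ones among up to 200 genes with the lowest p stood in for too few calls, so the gene set itself changed, and it was 0.019 at a mean of at least 5 FPKM (167 genes), 0.032 after quantile normalization (198), 0.096 when rescaled (200) and 0.401 with only genes above 0 in every library (79).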

Other observations

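The test of noncoding RNAs across both experiments was chosen only after the result was seen; for gene span, the trend over all genes had been seen but not its value among genes of like expression.

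HIST1H2BG and HIST1H2AE are adjacent on chromosome 6, between 26215159 and 26217483 in hg38. HIST1H2BG had 392.3 and 257.1 FPKM in wild type without and with etoposide and 4.75 and 0.411 FPKM in the libraries labelled knockout. HIST1H2AE had 244 and 318 FPKM in wild type and 9.54 and 3.58 FPKM in the libraries labelled knockout. The other 41 histone genes had a median log2 ratio of 0.13 in the untreated pair, from -0.52 to 0.52. In the immunoprecipitated RNA, HIST1H2BG had 38.8 FPKM in FLAG-empty replicate 2 and 16.9 and 11.7 FPKM with FLAG-RBM7.

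Long genes may lose RNA with etoposide whatever their expression, since a poisoned topoisomerase could stop transcription more often along a long gene. In each of 3 classes of expression and in both lines, genes over 100 kb lay below genes under 10 kb, with differences of the medians from -0.608 to -0.416. Across 10791 genes, which are not independent replicates, Spearman rho of span and response was -0.325 in wild type and -0.438 in the line labelled knockout. This is consistent with an effect of span, but elongation itself was not measured.

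RNAs bound by RBM7 might accumulate where it is missing. Across 275 noncoding genes, which are not independent replicates, the Pearson correlation of the log2 fold change with FLAG-RBM7 and the log2 ratio of the library labelled knockout over wild type was 0.215 untreated and 0.077 with etoposide. The test asked for a Pearson correlation of more than 0.2 in both pairs, which was not met. Spearman rho was 0.241 untreated and 0.161 with etoposide, so a weak relation is not excluded.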
